A study of Mus musculus with 6 samples.

How the data were processed

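Gene expression was measured by RNA sequencing of infarcted cortex from male wild-type C57 mice. Per the labels' protocols, a photothrombotic stroke (a clot made in cortical vessels by light after an intravenous agent) was induced in the left hemisphere with 100 mg/kg of the agent and a 532 nm laser of 250 mW, 1.5 mm wide, for 5 minutes. Saline or PLEA nanoparticles (100 µL) were injected into the tail vein 2 hours later, and the tissue was taken for the day 3 time point. The labels do not explain the abbreviation PLEA or name the intravenous agent. RNA was extracted with an RNeasy kit and 1.3 µg of it entered a SMARTer mRNA library preparation, per the labels' protocols.

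The authors deposited 1 table of raw read counts per gene, with 56748 genes and a column for each of the 6 libraries, and no normalization had been applied to its whole-number values. Gene length in bases stands beside the counts in the deposited table. The aligner, the counting tool and its strand setting are not given in the sources used here. The submitters' processing notes name GRCm38 and mm10 as builds, but of 52036 genes off the mitochondrial chromosome that are shared with GENCODE M21, an annotation of GRCm38, only 1435 (2.76%) had the same coordinates, while 37 of 37 mitochondrial genes did. Coordinates are therefore printed as the deposited table gives them, with no build attached. Samples were grouped by their titles into 3 saline and 3 PLEA libraries. The labels do not state that the replicates of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

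Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, the quasi-likelihood F test, group as the only term), with Benjamini-Hochberg adjustment over 17584 tested genes and a threshold of 0.05. Standard errors of log2 fold changes are the fold change divided by the square root of F. Every adjusted p for a gene is from this test unless another tool is named. CPM denotes the count scaled by the library's total and TMM factor. The 45 gene lists for cell types, neighbouring tissues, RNA quality and processes were fixed before the data were examined. Lists with at least 3 tested members (44 of them) were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over lists. Camera asks whether the genes of a list differ more than the other genes. The same lists were tested with an estimated correlation and with fry, which asks whether a list's genes move on balance in 1 direction. The preset value assumes nearly independent genes, so it gives smaller p-values where genes of a list vary together between libraries.

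Genes named in the text, except Ngp, follow a rule fixed before the data were examined. Up to 12 genes per direction were to be those past the threshold with a mean log2 CPM of at least 1 and no overlap between groups. With fewer than 5 passing, the 5 smallest p-values in each direction were taken at the same level, without predicted genes. Up to 4 members of each list with the smallest p were also eligible. Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, limma voom, no filter, a CPM of at least 1 in 3 libraries, an absolute log2 fold change of at least 1, protein-coding genes, a replicate block, a length offset (loess span 0.5) and leaving out each library. Alternatives added after seeing the data left out saline replicates 1 and 2 together, used the striatal marker level as a covariate, or used robust edgeR. Near-identical copies of mitochondrial genes were searched among GENCODE M21 transcripts with BLASTN (identity of at least 99%).

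The procedure was tested on simulated data with the means, dispersions and library sizes of this comparison, 17584 genes and 200 changed genes. In that simulation edgeR recovered 7.46% of genes changed 1.5-fold, 32.8% of those changed 2-fold and 81.8% of those changed 4-fold, and 5 of its 86 calls were unchanged genes. DESeq2 recovered 14.9%, 53.7% and 90.9%, and 40 of its 146 calls were unchanged genes. Totals ranged from 16810448 to 17516434 counts per library, and a gene at 10 CPM had about 168 counts in the smallest library, a counting error of 7.71%. No library pair agreed within sampling noise, which argues against repeat sequencing of the same preparation. This does not show that the libraries came from separate animals. Each library was treated as 1 sample.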

Results

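The data comprise 6 RNA-seq libraries of infarcted mouse cortex at day 3, 3 from mice given saline and 3 from mice given PLEA nanoparticles after photothrombotic stroke. No unlesioned tissue was analysed here, so values compare treatments and not stroke with health. Total counts were 16984630, 17516434 and 16810448 in saline replicates 1 to 3 and 17484650, 17451977 and 17357781 in PLEA replicates 1 to 3. The comparison asks how gene expression in tissue labelled as infarcted cortex differed after PLEA, in a study whose stated aims are thrombolysis and neuroprotection. How much of each piece was infarct was not measured here, so a difference need not lie within the infarct.

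The mean distance between 2 libraries, as the root mean square difference in log2 CPM, was 0.595 between groups and 0.579 within groups. The first principal component held 38.9% of the variance and ran from saline replicate 1 to PLEA replicate 2, and the second, with 28.0%, set saline replicate 2 apart. The difference of 0.0159 in mean distance had an exact one-sided permutation p of 0.3, where 0.1 is the smallest that 3 against 3 libraries can give.

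**Figure D1:**
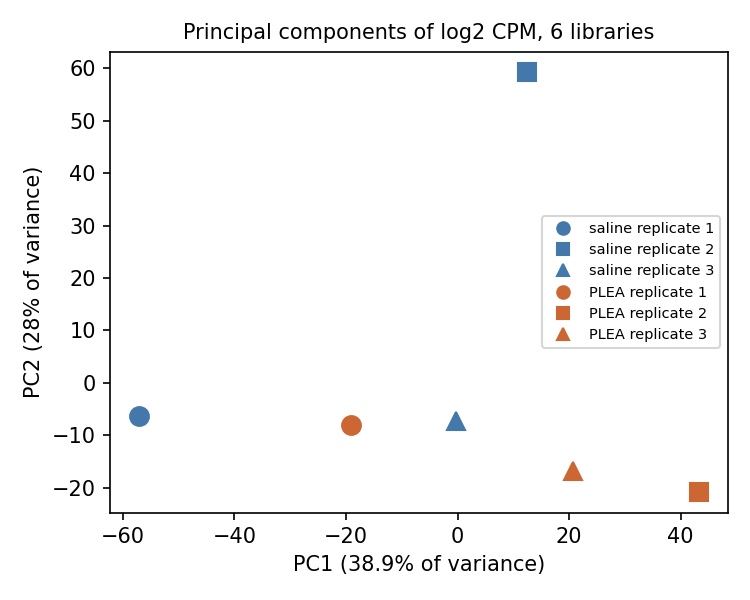
Each point is 1 library, placed by its first (x axis) and second (y axis) principal component of log2 CPM, with colour for treatment and shape for replicate. Saline replicate 2 stands alone at 59.2 on the second component, and the groups overlap on the first. On the second the PLEA libraries, at -8.02, -20.8 and -16.9, lie below the other saline libraries, at -6.26 and -7.29.

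No single gene passed the edgeR test between PLEA and saline. Of the 5 genes with the smallest p among those lower in PLEA, 1 is a member of the fixed meninges list. That gene, Aldh1a2, which makes retinoic acid, was at 15.3 ± 1.54 CPM (SD, n = 3) in saline and 5.29 ± 1.29 CPM (SD, n = 3) in PLEA, a log2 fold change of -1.53 (SE 0.22, adjusted p = 0.574). Slc13a4, a sulfate transporter, had a log2 fold change of -1.19 (SE 0.17), Bche, which encodes butyrylcholinesterase, -1.21 (SE 0.17) and Fbln1, a matrix protein, -1.03 (SE 0.16), with adjusted p = 0.574 for each. In the deposited table Aldh1a2 spans bases 71123071 to 71203525 of chromosome 9 and Slc13a4 bases 35244892 to 35285066 of chromosome 6.

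The fifth of these genes, mt-Nd4l, a mitochondrial subunit of respiratory complex I, was at 93.4 ± 39.6 CPM (SD, n = 3) in saline and 22.3 ± 3.01 CPM (SD, n = 3) in PLEA (log2 fold change -2.06, SE 0.32, adjusted p = 0.574). Its value is uncertain, because 294 of its 297 bases are identical to the pseudogene Gm10222 and reads can be split between them. Counts were 814, 1968 and 1927 in saline and 335, 448 and 398 in PLEA for mt-Nd4l. Gm10222 had 504, 268 and 492 in saline and 306, 299 and 222 in PLEA. The copy's PLEA counts are too few to close the gap. Reads that match both may have been left out of both counts, since the counting tool is not known. Ambiguous reads therefore stay open as a source of the difference. The neighbouring gene mt-Nd4 averaged 55363 counts per library, against 982 for mt-Nd4l, and had a log2 fold change of -0.48 (SE 0.17). The gene mt-Nd4l was the 1 gene past the threshold without saline replicate 1 (adjusted p = 0.00339).

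The 5 genes with the smallest p among those higher in PLEA did not pass either. Sdk2, a synaptic adhesion molecule, was at 37.7 ± 3.42 CPM (SD, n = 3) in saline and 62.6 ± 2.33 CPM (SD, n = 3) in PLEA (log2 fold change 0.73, SE 0.12, adjusted p = 0.574). Ptgs2, which encodes the prostaglandin enzyme COX-2, had a log2 fold change of 0.70 (SE 0.15), Lamp5, a marker of a class of cortical interneurons, 0.45 (SE 0.10) and Sf3b3, a splicing factor subunit, 0.53 (SE 0.13), with adjusted p = 0.818 for each. The keratin gene Krt80 had a log2 fold change of 1.28 (SE 0.24, adjusted p = 0.818). Its span, introns included, overlaps the antisense gene Gm35853 over 22719 bases. Overlap of their exons was not checked, so Gm35853 reads among its counts cannot be excluded without strand. For each of these 10 genes the 3 PLEA libraries lay on 1 side of the 3 saline libraries.

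**Figure D2:**
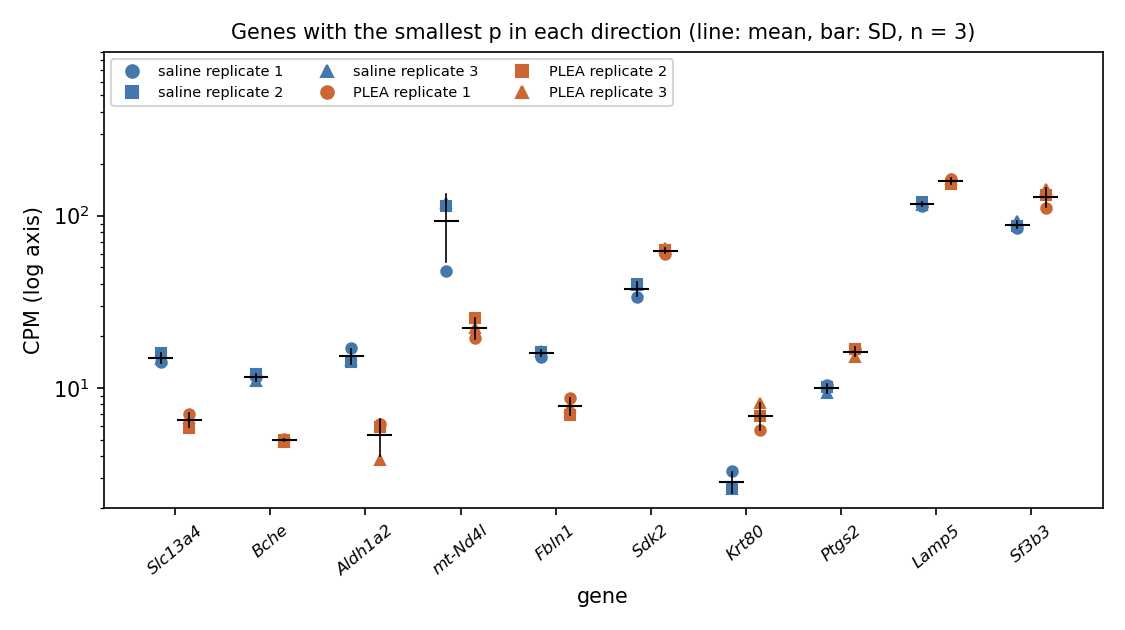
CPM on a log axis for the 5 genes with the smallest p in each direction, with 1 point per library, a line for each group mean and a bar for its SD (n = 3). The groups do not overlap for any of the 10 genes, and none passed in edgeR after adjustment, while DESeq2 called 7 of them.

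The edgeR quasi-likelihood test called 0 genes higher and 0 lower, against 401 higher and 630 lower at an unadjusted p under 0.05. Of the 10 splits of the libraries into 3 and 3, 4 gave at least that sum of 1031, the real one among them, and the highest gave 1974. DESeq2 called 2 higher (Sdk2 and Krt80) and 37 lower, among them Aldh1a2, Slc13a4, Bche, Fbln1, Dcn and Col1a1, and limma voom called 0 in each direction. Without the expression filter edgeR called 7 higher and 31 lower. Groups did not overlap for 908 genes higher and 974 lower in PLEA, or 10.7% of tested genes, where chance gives 10%.

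Among the fixed lists, camera called 1 higher and 10 lower in PLEA. None of the 11 calls held with an estimated correlation, where the smallest adjusted p was 0.470, or with fry, where it was 0.180. In a simulation with independent genes, 9 genes of 1 list were given a log2 fold change of -1. With an estimated correlation that list had camera adjusted p = 0.0458, against 3.33e-16 at the preset one. The simulated genes were independent, whereas the estimated correlation was 0.169 for the meninges list, 0.695 for interferon-response genes and 0.963 for homeostatic microglia genes. The simulation therefore cannot say how much a failure with an estimated correlation weighs against a call in lists of correlated genes. In such lists the preset correlation gives p-values that are too small. In edgeR no member of any list passed over all genes tested, while DESeq2 called list members such as Dcn, Col1a2, Oasl2, Cd74, Kcnj10 and mt-Nd2.

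The meninges list, markers of the membranes around the brain, had the lowest median. Its 8 tested genes had a median log2 fold change of -1.30 (camera adjusted p = 5.22e-09, adjusted p = 0.470 with an estimated correlation), and 6 were lower when adjusted over the list alone. Dcn, a collagen-binding proteoglycan, had a log2 fold change of -1.48 (SE 0.27), and the transporters Slc22a6 and Slc6a13 had -1.47 (SE 0.33) and -0.94 (SE 0.21), with edgeR adjusted p = 0.818 for each. The matrix list, which shares Dcn with it, had a median of -0.89 over 12 genes (camera adjusted p = 3.68e-05, adjusted p = 0.831 with an estimated correlation), with 5 lower when adjusted over the list alone. The fibrillar collagen genes Col1a1, Col1a2 and Col3a1 had log2 fold changes of -1.45 (SE 0.35), -1.05 (SE 0.22) and -1.69 (SE 0.43). Saline replicate 1 was the highest library for the meninges and the matrix list. Without it their medians were -1.01 and -0.64 (camera adjusted p = 7.18e-07 and 0.00211).

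Interferon-response genes had a median log2 fold change of -1.20 over 13 tested genes, all with negative values (camera adjusted p = 7e-09, adjusted p = 0.831 with an estimated correlation), and 6 were lower when adjusted over the list alone. The antiviral genes Oasl2, Ifit1 and Ifit3 had log2 fold changes of -1.48 (SE 0.30), -1.28 (SE 0.29) and -1.33 (SE 0.35), and the transcription factor Irf7 had -1.48 (SE 0.39), though it overlaps the opposite-strand gene Phrf1 over 45 bases. Antigen-presentation genes had a median of -0.65 over 9 genes (camera adjusted p = 0.000144, adjusted p = 0.831 with an estimated correlation), with 3 lower when adjusted over the list alone. Cd74, the class II invariant chain, was at 6.42 ± 5.69 CPM (SD, n = 3) in saline and 1.31 ± 0.159 CPM (SD, n = 3) in PLEA. The class II genes H2-Eb1 and H2-Aa were under 5 CPM in all libraries. B2m, the class I light chain, had a log2 fold change of -0.65 (SE 0.27), and without saline replicate 1 B2m was at -0.25 and Cd74 at -1.25. Saline replicate 1 was the highest library in both lists, and without it the medians were -0.48 and -0.25. Without saline replicate 2 the antigen-presentation median was -1.54, and without PLEA replicate 1 or 3 it was -1.31 or -1.08, each over 11 genes, since 2 more members passed the filter in those fits.

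Homeostatic microglia genes had a median of -0.77 over 11 genes, all with negative values (camera adjusted p = 8.85e-05, adjusted p = 0.831 with an estimated correlation), and 0 passed when adjusted over the list alone, with 2 lower at an unadjusted p under 0.05. P2ry12, a purine receptor of resting microglia, had a log2 fold change of -1.56 (SE 0.54), Siglech -1.38 (SE 0.49) and the transcription factor Sall1 -0.54 (SE 0.26). The span of P2ry12, introns included, lies over 46600 bases inside that of the opposite-strand gene Med12l. Overlap of their exons was not checked, so Med12l reads among its counts cannot be excluded without strand. Without saline replicate 1 the values were -1.02 for P2ry12, -0.87 for Siglech and -0.29 for Sall1, without PLEA replicate 1 P2ry12 was at -2.41, and without PLEA replicate 2 Sall1 was at -0.32. Saline replicate 1 was the highest and PLEA replicate 2 the lowest library for each of the 11 genes. The median was -0.29 without saline replicate 1, -0.51 without PLEA replicate 2 and -1.23 without PLEA replicate 1. Inflammasome genes had a median of -0.40 over 9 genes (camera adjusted p = 0.0192, adjusted p = 0.831 with an estimated correlation), with Casp1 at -0.97 (SE 0.54) and its adaptor Pycard at -1.26 (SE 0.72). Without saline replicate 1 Casp1 was at -0.23 and Pycard turned to 0.0025, and Pycard overlaps the antisense gene Gm45205 over 599 bases. That call was lost without saline replicate 1 (median -0.02, camera adjusted p = 0.65) and without PLEA replicate 2 (median -0.31 over 10 genes, camera adjusted p = 0.18).

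Homeostatic astrocyte genes had a median of -0.34 over 11 genes (camera adjusted p = 0.000217, adjusted p = 0.831 with an estimated correlation), and 4 were lower when adjusted over the list alone. The gap junction gene Gja1 had a log2 fold change of -0.68 (SE 0.16), the potassium channel gene Kcnj10 -1.01 (SE 0.26), the glycolytic gene Aldoc -0.51 (SE 0.14) and the water channel gene Aqp4 -1.18 (SE 0.34). Mural cell genes had a median of -0.36 over 8 genes (camera adjusted p = 0.0102, adjusted p = 0.831 with an estimated correlation), including Rgs5 at -0.66 (SE 0.28) and Vtn at -0.38 (SE 0.16). Angiogenesis genes had a median of -0.28 over 12 genes (camera adjusted p = 0.0123, adjusted p = 0.831 with an estimated correlation), including the VEGF receptor genes Kdr at -0.75 (SE 0.28) and Flt1 at -0.55 (SE 0.22). The mural and angiogenesis calls were lost without saline replicate 1 (medians -0.18 and -0.19, camera adjusted p = 0.14 and 0.12), and the angiogenesis call also without PLEA replicate 2 (median -0.21, camera adjusted p = 0.14). Without saline replicate 1 Aqp4 was at -0.78 and Rgs5 at -0.22, and without PLEA replicate 2 Vtn was at -0.24 and Flt1 at -0.33. With saline replicates 1 and 2 both left out, an alternative chosen after seeing the data, the astrocyte call was lost too (median -0.11, camera adjusted p = 0.225), but this sets saline replicate 3 alone against PLEA and assumes that it varies like the PLEA libraries. The astrocyte median was -0.54 without saline replicate 3, and the angiogenesis median was -0.55 without PLEA replicate 1.

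Genes of the mitochondrial chromosome had a median of -0.51 over 13 genes, all with negative values (camera adjusted p = 7e-09, adjusted p = 0.831 with an estimated correlation), with 3 lower when adjusted over the list alone. The complex I genes mt-Nd2 and mt-Nd3 had log2 fold changes of -0.67 (SE 0.18) and -0.77 (SE 0.20), and mt-Nd3 shares 345 bases at 99.7% identity with the copy Gm28438 and was at -0.49 without saline replicate 1. The mitochondrial chromosome held 5.76% ± 1.18 (SD, n = 3) of counts in saline and 4.39% ± 0.513 (SD, n = 3) in PLEA, an exact permutation p of 0.2. Nuclear genes of oxidative phosphorylation had a median of -0.06 over 16 genes, with camera adjusted p = 0.662.

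Striatal markers had a median of 0.51 over 9 genes, all with positive values (camera adjusted p = 0.0103, adjusted p = 0.831 with an estimated correlation), and 0 passed in edgeR when adjusted over the list alone or at an unadjusted p under 0.05. Ppp1r1b, which encodes DARPP-32 of striatal projection neurons, was at 189, 25.8 and 411 CPM in saline replicates 1 to 3 and at 202, 533 and 436 CPM in PLEA replicates 1 to 3. The dopamine receptor gene Drd1 was at 5.66 CPM in saline replicate 2 and at 38.8 CPM or more in the others. The call was lost without saline replicate 2 (median 0.11, camera adjusted p = 0.69) and without PLEA replicate 2 (median 0.33, camera adjusted p = 0.07), and the median was 1.51 without saline replicate 3. Against saline replicate 3 alone it turned to -0.42, a value that rests on 1 saline sample.

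**Figure D3:**
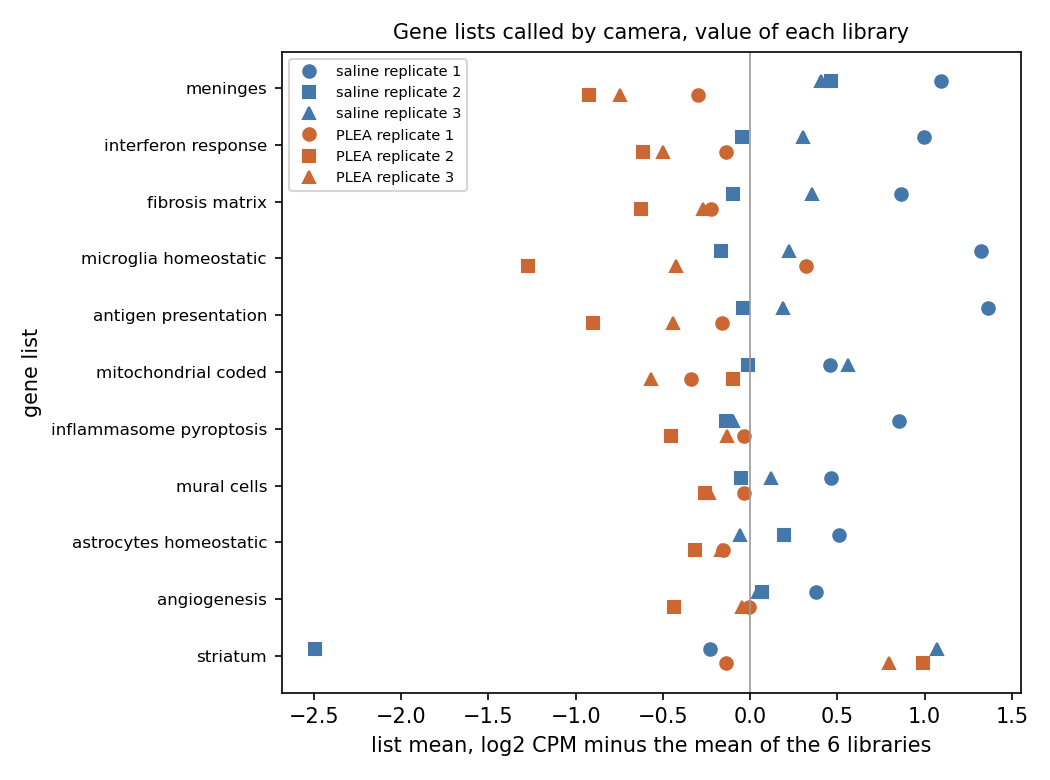
For each of the 11 lists called by camera, each point is the mean log2 CPM of the list's genes in 1 library minus the mean of the 6 libraries (x axis). Saline replicate 1 is the highest library in 9 of the 11 lists shown, as it is in 29 of all 45, and saline replicate 2 lies at -2.49 in the striatal list.

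Neuronal and stress lists showed no call. Median log2 fold changes were 0.06 for excitatory neurons, 0.05 for inhibitory neurons, -0.01 for synaptic genes, -0.03 for the unfolded protein response, -0.06 for heat shock, -0.05 for hypoxia and glycolysis, -0.16 for pro-apoptotic genes, -0.07 for ferroptosis and 0.12 for neurotrophic genes. Immediate early genes had a median of 0.11 over 14 genes, and 2 were higher when adjusted over the list alone, the activity-induced transcription factors Fosb at 0.61 (SE 0.16) and Npas4 at 0.88 (SE 0.24). Egr3 was at 0.53 (SE 0.18), or 0.34 without PLEA replicate 1. Dusp1, which overlaps the opposite-strand gene Ergic1 over 640 bases, was at -0.49 (SE 0.21), or -0.32 without saline replicate 2. NRF2 antioxidant genes had a median of 0.01 over 15 genes. In that list the haem-degrading enzyme gene Hmox1 ranged from 6.24 to 37.8 CPM in saline and from 15.1 to 107 CPM in PLEA, Slc7a11, a cystine transporter, had a log2 fold change of -0.56 (SE 0.19) and catalase (Cat) -0.34 (SE 0.13).

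The coagulation, platelet, endothelial barrier, endothelial activation, matrix protease and complement lists showed no call. Coagulation and fibrinolysis genes had a median of -0.32 over 14 genes with camera adjusted p = 0.196, including the clot-stabilising factor F13a1 at -1.08 (SE 0.41), or -0.53 without saline replicate 1, the protease inhibitor Serpine2 at -0.29 (SE 0.11) and tissue plasminogen activator (Plat) at 0.28 (SE 0.14). Medians were 0.04 for platelets, -0.22 for endothelial barrier genes, -0.22 for endothelial activation and -0.10 for matrix proteases. Complement genes had a median of -0.55 over 10 genes with camera adjusted p = 0.0726, and the C1 inhibitor gene Serping1 was lower when adjusted over the list alone (log2 fold change -0.79, SE 0.19).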

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

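The alternatives that left out saline replicates 1 and 2 together, used the striatal covariate or used robust edgeR were chosen after seeing the data. Counts of genes higher and lower were 0 and 0 with RLE or upper-quartile factors, limma voom, the stricter CPM filter, protein-coding genes, the length offset, the striatal covariate and robust edgeR. DESeq2 called 2 higher and 37 lower and edgeR without a filter 7 and 31, and the cause was not tested. Leaving out 1 library gave 0 to 0 genes higher and 0 to 1 lower, and leaving out saline replicates 1 and 2 gave 0 higher and 2 lower. Lists called higher and lower numbered 0 and 0 with an estimated correlation and 0 and 0 with fry, against 1 and 10. Leaving out 1 library gave 1 to 2 lists higher and 8 to 18 lower, with 18 lower without saline replicate 2 and 2 higher without saline replicate 1 or 3. Without saline replicates 1 and 2 together, which leaves 1 saline sample assumed to vary like the PLEA libraries, 2 lists were higher and 11 lower, the striatal median turned to -0.42, and log2 fold changes turned for Ppp1r1b to -0.068, Drd1 to -0.16, Casp1 to 0.027, Pycard to 0.50 and Mki67 to 0.19. Leaving out 1 library gave -1.74 to 0.0025 for Pycard and -2.63 to 0.37 for Mki67, the highest without saline replicate 1 and the lowest without PLEA replicate 1. Pairing by replicate number stays unresolved. Correlations of same-numbered deviations were 0.37, 0.17 and -0.02, and those of differently numbered ones ran from -0.36 to 0.23. With the replicate block 0 genes were higher and 0 lower, 1 list was higher and 14 lower, and the striatal median was 0.83. For 56 of the genes named in the text, 967 of 1007 alternative values kept direction and side of the threshold, 33 newly passed and 7 turned. For the 11 lists, 108 of 143 did, 34 no longer passed and 1 turned. The biological coefficient of variation was 22.8%, and in the simulation of this comparison edgeR found 32.8% of 2-fold changes, so changes of that size can be missed.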

Other observations

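The tests of saline replicate 1 as a source, the comparison of excitatory with striatal genes and the striatal covariate were chosen after the data were seen, while leaving out each library was planned. The neutrophil list summed to 425, 182 and 498 counts in saline replicates 1 to 3 and to 176, 79 and 147 in PLEA. Of these, Csf3r gave 380, 117 and 125 in saline and 141, 52 and 103 in PLEA. The lymphocyte list summed to 178, 63 and 333 in saline and to 159, 393 and 275 in PLEA. Of these, Cd4 gave 116, 15 and 280 in saline and 136, 344 and 234 in PLEA. Single genes thus made up most of these sums in most libraries, so the sums are weak measures of these cell types. The granule protein gene Ngp, chosen after its values were seen, had 115 counts in saline replicate 3 and at most 4 in any other library. Csf3r, a neutrophil and microglial receptor gene, ranged from 6.76 to 22.3 CPM in saline and from 2.95 to 8.15 CPM in PLEA. The 17 cytokine and chemokine genes summed to between 227 and 514 counts per library, of which Ptgs2 gave between 151 and 296, and the 7 red cell genes summed to between 13 and 58. Monocyte and macrophage genes had a median log2 fold change of -0.58 over 5 genes, lymphocyte genes -0.05 over 3, red cell genes 0.52 over 3, cytokine genes -0.30 over 3 and neutrophil genes -0.91 over 2, the last too few for camera.

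List means of reactive astrocyte and proliferation genes varied between libraries within both groups. Their SDs (n = 3) were 0.866 and 1.42 log2 CPM in saline and 0.998 and 1.36 in PLEA. Gfap, the astrocyte filament gene, was at 1683 CPM in saline replicate 1 and between 109 and 489 CPM in the other libraries. Mki67, a marker of dividing cells, was at 48.0 CPM in saline replicate 1, 20.3 CPM in PLEA replicate 1 and lower elsewhere. Median log2 fold changes were -0.02 for reactive astrocytes, -0.41 for damage-associated microglia, -0.15 for reparative macrophages, -0.56 for NADPH oxidase, 0.00 for TLR and NF-kB genes and -1.02 for proliferation, none called by camera. They were -0.21 for myelin, -0.12 for oligodendrocyte precursors, 0.01 for skeletal muscle and 0.27 for nuclear long noncoding RNAs. Ttr, a choroid plexus gene, was at 281 CPM in PLEA replicate 3 and at most 5.55 CPM in the others, and the choroid plexus list had a median of 0.51.

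Lower meningeal genes in PLEA may reflect a smaller share of meninges in those pieces. A second list of 20 leptomeningeal genes, written before its values were seen, had a median log2 fold change of -0.72 with quartiles of -0.87 and -0.44, past its bound of -0.65 by less than that spread. More striatum in the PLEA pieces is argued against, since the meninges median was -1.29 with the striatal level as a covariate. Less scar activation of fibroblasts stays open: 8 scar genes had a median of -0.074 (quartiles -0.48 and 0.018), which met the bounds set beforehand against it (-0.3 and 0) by less than that spread, a condition added afterwards. An effect of PLEA on meningeal cells was not tested apart from the amount of tissue.

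Lower microglial, antigen-presentation and interferon values may rest in part on saline replicate 1, a library highest in 29 of all 45 lists. It also stood apart in ribosomal RNA, at 0.906% of counts against at most 0.521% in the others, and in mitochondrial counts, at 7.01% against at most 5.61%. Without it the medians shrank to -0.29, -0.25 and -0.48, below 0.5 of their sizes, while camera still called each list at its preset correlation, and with all libraries none was called at an estimated one (adjusted p = 0.831 for each). The tests therefore leave open how much of each difference belongs to that library. Whether its RNA quality or the tissue in that piece sets it apart was not tested. Gfap, at 1683 CPM, and Mki67, at 48.0 CPM, were also highest there. A response to PLEA stays open and untested.

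Higher striatal markers in PLEA may reflect a different amount of striatum in the dissected pieces. Saline replicate 2, the lowest library for all 9 fixed striatal genes, was also the lowest in 92.9% of a second list of 14, written before its values were seen. Genes of 1 cell type vary together, so this cannot separate the amount of striatum from the survival or state of striatal neurons, which stays open. Excitatory cortical genes did not rise by as much as a set, with a median of 0.062 and an upper quartile of 0.17, against 0.51 for striatal genes. They moved both ways, with 8 positive and 4 negative values, among them Gria1 at 0.35 (SE 0.19) and Rorb at -0.59 (SE 0.22). That 0.51 rests largely on saline replicate 2, without which it was 0.11. CPM values are shares, so more striatum in a piece could hide a rise of cortical genes. The comparison therefore cannot decide whether more neurons survived throughout the pieces.

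The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05. The real split gave 0 genes higher and 0 lower in edgeR, and the highest other split gave 1, but against a real count of 0 the comparison says nothing. It gave 1 list higher and 10 lower, and the highest other split gave 22 in 1 direction, with at least as many in 10 and 6 of the 10 splits. DESeq2 called 39 genes for the real split, and 4 of the 10 splits gave at least as many, the real one among them. The highest count was 212, for the split of saline replicates 1 and 3 with PLEA replicate 1 against the rest. For that split edgeR called 0 higher and 0 lower.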
